A study of Homo sapiens with 32 samples.

How the data were processed

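The series measured messenger RNA in 4 human T-cell lines after 96 hours in culture with romidepsin, azacitidine, both drugs or neither. Romidepsin inhibits histone deacetylases, and azacitidine is a cytidine analogue that is built into nucleic acids and traps DNA methyltransferases. Per the labels, PF382 is a line of T-cell acute lymphoblastic leukemia, TLOm1 of adult T-cell leukemia, and HH and H9 of cutaneous T-cell lymphoma. Cells were in logarithmic growth, romidepsin was added once at the start and azacitidine once a day, per the labels' protocols.

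RNA was extracted with a Qiagen RNeasy kit, stranded libraries were made with the Illumina TruSeq Stranded mRNA kit and sequenced on a NextSeq 500, per the labels. The labels name both poly(A) RNA and ribosomal RNA depletion, so the selection step is not settled here. STAR, DESeq2 and limma are named with the build GRCh37.p2, per the submitters' processing notes, without versions or the step each served. The read counter, the gene annotation and the strand setting are not given in the sources used here. The deposited values are raw counts per gene symbol, 1 table per library, with 25559 symbols in each of the 32 tables. They were whole numbers with totals that differed between libraries, and they were used as deposited. Every symbol named a gene, and no column was left unused.

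Each cell line gave 8 libraries: untreated, romidepsin, azacitidine at 3 doses, and romidepsin with azacitidine at the same 3 doses. The azacitidine doses were 125, 250 and 500 nM in PF382 and TLOm1, and 50, 125 and 250 nM in HH and H9. Titles of the combinations give doses without a unit, which were read as nM. Romidepsin was at 1.25 nM in PF382 and at 1 nM in TLOm1 and H9. For HH the titles give 1 nM alone and 1.25 nM in the combinations. One PF382 title misspells the line, and its cell line label was followed. There was 1 library per condition in each line, so the 4 cell lines served as replicates (n = 4). The spread behind the p-values was pooled over all 32 libraries of a fit, with the libraries of a line counted as independent. It is not the spread of the 4 line changes of a comparison alone, nor that between cultures of a line. Sequencing batches are not given in the sources used here.

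Total counts ran from 16175077 (HH, azacitidine 50 nM) to 32496676 (HH, azacitidine 125 nM). A floor of 3 counts was 0.131 CPM (counts relative to the library total) in the untreated PF382 library, and floors and counting intervals (95%, exact Poisson ratio) cover counting error only, since reads carry no molecular identifiers.

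Groups were compared with edgeR's quasi-likelihood F test in R 4.3.3 (edgeR 4.0.16, limma 3.58.1), with TMM scaling, robust dispersions, Benjamini-Hochberg adjustment and an adjusted p under 0.05 as the threshold. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 17801 symbols. Every adjusted p for a gene below comes from this test unless another tool is named. All 32 libraries entered each fit. The first model had the 10 groups of treatment and dose plus cell line as a term (19 residual degrees of freedom). At 250 nM, the highest azacitidine dose given to 4 of 4 lines, it compared romidepsin, azacitidine and the combination with untreated cells, the combination with each drug, and the departure of the combination from the sum of the single-drug log2 changes. A second model gave the change per doubling of the azacitidine dose within a line. The line model for romidepsin gave its effect in each line (4 libraries with against 4 without, matched on azacitidine dose, 12 residual degrees of freedom), and the line model for azacitidine gave its effect in each line (6 libraries against 2, any dose, matched on romidepsin being given or not). In HH the labels give 1 nM romidepsin alone and 1.25 nM in the combinations, so that match is not of equal doses there. Both tested whether the 4 line effects were equal.

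Libraries were paired by cell line, which is the origin of the cells. After group means were removed, 60 of 60 pairs of same-line libraries from different groups, taken among the 6 groups present in each line, correlated across genes, at 0.86 to 0.973. Each of the 32 libraries lay closest to another library of its own line, and none was identical to another: the closest pair differed by a chi-square of 5.09 per gene, several times sampling noise.

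The 31 gene lists were X-linked cancer testis antigens, autosomal germline genes, interferon-stimulated genes, nucleic acid sensors, genes of endogenous retroviral origin, MHC class I, MHC class II, checkpoint and costimulatory molecules, T-cell receptor and identity genes, cytokines and chemokines, pro-apoptotic genes, anti-apoptotic genes, p53 targets, cell cycle genes, inhibitors of cyclin-dependent kinases, histone genes, metallothioneins, neuronal genes, epigenetic enzymes, drug handling genes, MYC and ribosome biogenesis, cholesterol synthesis and uptake, the ATF4 and endoplasmic reticulum stress response, NF-kB targets, imprinted genes, and markers of cytotoxic and natural killer cells, B cells, myeloid cells, erythroid cells and megakaryocytes, fibroblasts and epithelium. Each was tested with limma's camera on voom values (preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists), and again with an estimated correlation. The groups, designs, lists, the rule for named genes and the alternatives were fixed before the data were examined.

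Named genes are, for each comparison at 250 nM, the 8 with the largest change in each direction among those called, with 1 sign in 4 of 4 lines and a mean log2 CPM of at least 1. For slopes and line effects they are the 4 largest in each direction, for tests between lines the 4 with the largest F, and for each list the 4 tested members with the smallest p. Symbols without a gene name of their own, such as those starting with LOC, were passed over, DNMT1, DNMT3A, DNMT3B and HDAC1 to HDAC3 are given as drug targets, and XIST and Y-linked genes are left out. A few other genes that this rule names are not reported here. A gene at 0 counts in a whole group has its fold given as a bound against 3 counts over the group, and a gene at 1 to 3 counts has a ratio of summed CPM with a counting interval.

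The scripts were tested on simulated data with known changes in 200 of 17801 genes. The changed genes had a mean log2 CPM of at least 1, and in comparisons over lines each change was the same in every line. For romidepsin against untreated, 77 of 100 genes changed 2-fold and 89 of 100 changed 4-fold were recovered, with 11 false calls. For the departure from additivity the numbers were 67 and 86, with 22 false calls. For the azacitidine slope they were 94 and 98, with 19 false calls. For the romidepsin effect in H9 they were 94 and 96, with 8, and for the azacitidine effect in H9 75 and 92, with 7. Simulated libraries without any effect gave 0 calls in each line. In the simulations of the departure from additivity and of the slope, false calls were a larger share of calls than the threshold of 0.05 aims at.

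Alternatives were DESeq2 1.42.0, limma-voom, RLE and library-total scaling, no filter and a stricter filter (1 CPM in 8 libraries), no cell line term, only the groups compared, doses grouped by each line's own order, 125 nM in place of 250 nM, a linear dose, a line's libraries alone, and each line or dose left out in turn. Reads of near-identical gene copies (MAGEA2 and MAGEA2B, MAGEA3 and MAGEA6, CTAG1A and CTAG1B, SSX2 and SSX2B, the GAGE, XAGE1 and CSAG families, HLA and histone genes) can be split or lost by counting, so single members are uncertain. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart. A genome annotation of another build (GENCODE v29) was used for gene names only, and no coordinates are given.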

Results

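RNA was sequenced in 32 libraries from 4 human T-cell lines, with 8 treatments per line and 1 library per treatment. PF382 is a T-cell acute lymphoblastic leukemia line, TLOm1 an adult T-cell leukemia line, and HH and H9 are cutaneous T-cell lymphoma lines. Cells were left untreated or were exposed for 96 hours to romidepsin, to azacitidine at 3 doses, or to romidepsin with azacitidine at the same 3 doses. Azacitidine was given at 125, 250 and 500 nM to PF382 and TLOm1 and at 50, 125 and 250 nM to HH and H9, so 250 nM is the highest dose given to all 4 lines. Romidepsin was given at 1.25 nM to PF382, at 1 nM to TLOm1 and H9, and to HH at 1 nM alone and 1.25 nM in the combinations, per the labels. The series title names cell death, cancer testis antigens and immune modulatory pathways as its subjects, and the comparisons below ask how each drug and their combination changed gene expression. Total counts per library ran from 16175077 to 32496676, and 17801 gene symbols had enough counts to be tested. The largest component of variation over all libraries held 44.9% of the variance and set PF382 and H9 apart from TLOm1 and HH. Changes are log2 fold changes over the 4 lines (n = 4) unless a single line is named, each ± a standard error. That error is the size of the change divided by the square root of its F value. It comes from the fit of all 32 libraries, not from the 4 line changes alone. A gene is called at an adjusted p under 0.05 by edgeR's quasi-likelihood test.

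Romidepsin alone raised 3 genes and lowered 0 of 17801 over the 4 lines. ZNF365, a zinc finger protein of the centrosome, rose by 2.08 ± 0.30 (adjusted p = 0.00983). NXPH4, a neurexophilin that binds neurexins, rose by 2.04 ± 0.32 (adjusted p = 0.0143), and NRGN, the postsynaptic calmodulin-binding protein neurogranin, by 1.29 ± 0.22 (adjusted p = 0.0384), each in 4 of 4 lines. Each lost its call in fits without 1 line: ZNF365 without PF382 (adjusted p = 0.153), HH (0.26) or H9 (0.13), NXPH4 without PF382 (0.294), TLOm1 (0.344) or HH (0.26), and NRGN without PF382 (0.452), TLOm1 (0.086), HH (0.494) or H9 (0.173). No gene at all was called without PF382 or without HH, with 0 in each fit. DESeq2 called 9 genes (7 higher, 2 lower) and limma-voom 9 (8 higher, 1 lower), and 998 genes (5.61%) had an unadjusted p under 0.05.

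None of the 31 gene lists had a member called after romidepsin alone over all genes. Of 47 neuronal genes, many of which are silenced in other cell types by the repressor REST, 2 were higher when adjusted over the list alone, and 40 had a positive estimate. Among them were MAP2, a microtubule protein of neurons, at 3.15 ± 0.59 (adjusted p = 0.0659 over all genes), and CHGB, a chromogranin of secretory granules, at 1.89 ± 0.40 (adjusted p = 0.14). The list was higher than other genes (camera adjusted p = 0.0107), and adjusted p = 0.0873 with an estimated correlation. Of 31 checkpoint and costimulatory genes 3 were higher and 1 lower over the list alone, among them CD274, which encodes the PD-L1 ligand, at 2.33 ± 0.44 in 4 of 4 lines (adjusted p = 0.0659 over all genes). Of 23 genes of cholesterol synthesis and uptake 22 had a negative estimate, with 1, lanosterol synthase (LSS, -0.42 ± 0.12), lower over the list alone (camera adjusted p = 4.82e-08, and adjusted p = 0.326 with an estimated correlation). The lists of NF-kB targets and of epigenetic enzymes were lower (camera adjusted p = 0.001 and 0.0241), with adjusted p = 0.304 and 0.0873 with an estimated correlation, and the NF-kB call ended without HH (adjusted p = 0.1). The call of the epigenetic enzymes ended without PF382 (adjusted p = 0.0851) or without TLOm1 (adjusted p = 0.121).

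Azacitidine at 250 nM raised 685 genes and lowered 381, and many of the largest increases were in genes whose expression is usually limited to the testis. MAGEC1, an X-linked melanoma antigen gene, had 0 counts in the 4 untreated libraries and 366 in the 4 treated, at least 119-fold higher. MAGEA4, of the same family, went from 1 to 342 counts (ratio 334, counting interval 59.5 to 13231). SSX1 and SSX3, transcriptional repressors of another X-linked family, went from 3 to 696 (ratio 227, interval 77.2 to 1100) and from 3 to 534 counts (ratio 174, interval 59.2 to 846). PNMA5, a gene of the Gag-derived paraneoplastic antigen family, rose by 7.38 ± 0.67 (adjusted p = 7.07e-07), BRDT, the bromodomain protein of spermatogenesis, by 6.37 ± 0.50 (adjusted p = 8.37e-08), and DAZL, an RNA-binding protein of germ cells, by 5.98 ± 0.93 (adjusted p = 0.000422). The imprinted RNA H19 went from 1 to 1091 counts (ratio 1070, interval 191 to 42123), but the change rested on HH, and without it the estimate was 3.21 (adjusted p = 0.177).

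Of the genes called after azacitidine at 250 nM, 379 were at least 2-fold higher and 73 at least 2-fold lower. ALDOC, a fructose-bisphosphate aldolase, fell by 2.19 ± 0.42 (adjusted p = 0.00321), and HMGCS1, the synthase of hydroxymethylglutaryl-CoA in the mevalonate pathway, by 1.95 ± 0.33 (adjusted p = 0.000906). The uncharacterised gene C6orf223 fell by 2.08 ± 0.33 (adjusted p = 0.00056), and WNK4, a kinase of ion transport, by 1.74 ± 0.27 (adjusted p = 0.000387). PFKFB4, which sets the level of an allosteric activator of glycolysis, fell by 2.85 ± 0.72, and by 2.88, 2.92 and 2.42 without PF382, HH and H9, where it was not called (adjusted p = 0.0924, 0.0971 and 0.12). GRIP2, a glutamate receptor scaffold, fell by 2.73 ± 0.60 with all lines and by 1.22 without H9 (adjusted p = 0.308). AK4, a mitochondrial adenylate kinase, fell by 1.99 ± 0.50 and was not called without PF382 (-0.98, adjusted p = 0.155), HH (-2.01, 0.0758) or H9 (-2.18, 0.134), and DDIT4, a stress-induced inhibitor of mTOR, fell by 1.70 ± 0.47 and was not called without PF382 (-1.19, 0.193), HH (-1.68, 0.122) or H9 (-1.75, 0.14). The number of genes called was 679 without PF382, 601 without TLOm1, 479 without HH and 454 without H9. A fit of the 8 compared libraries alone called 30 genes, and grouping doses by their order in each line called 1940 at the highest dose.

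Of the X-linked cancer testis antigens, 31 of 49 tested rose and 0 fell after azacitidine at 250 nM, with 40 higher when adjusted over the list alone. That list had 94 genes in the data, and 49 passed the count filter, which genes can pass on treated libraries alone. In untreated PF382, TLOm1, HH and H9, 0, 1, 3 and 3 of the 94 had at least 10 counts. Most tested members could thus hardly fall, and shares of this list, here and below, are of genes the filter kept. CTAG2 (333 counts after treatment, at least 108-fold higher) and MAGEA1 (382 counts, at least 124-fold higher) had 0 counts in the untreated libraries, and each was higher in 3 of 4 lines. Of 47 autosomal germline genes 15 rose and 0 fell (20 over the list alone). They included CTCFL, the testis paralog of CTCF, from 3 to 195 counts (ratio 63.5, interval 21.4 to 310), TDRD1, a Tudor protein of the piRNA pathway, from 1 to 89 counts (ratio 86.9, interval 15.2 to 3471), and MAEL, of the same pathway, by 5.57 ± 0.76 (adjusted p = 0.000128). Of 23 genes of cholesterol synthesis and uptake 19 fell and 0 rose (21 lower over the list alone), among them squalene synthase (FDFT1, -1.15 ± 0.18, adjusted p = 0.000364), MVD of the mevalonate pathway (-1.03 ± 0.16, adjusted p = 0.000387) and LSS (-0.73 ± 0.12, adjusted p = 0.000685). By camera the adjusted p was 1.34e-24, 1.07e-09 and 2.33e-24 for these lists, and adjusted p = 0.0395 for each with an estimated correlation. The calls with an estimated correlation ended for these lists in the same order without PF382 (adjusted p = 0.108, 0.0739 and 0.0739), TLOm1 (0.0929 for each) or HH (0.0665, 0.0662 and 0.0662), and for cholesterol genes without H9 (0.103).

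Immune gene groups changed in few members after azacitidine at 250 nM. Of 44 interferon-stimulated genes 3 rose (3 over the list alone, camera adjusted p = 0.0857): IRF7 by 1.08 ± 0.24 (adjusted p = 0.00902), HERC6 by 0.83 ± 0.20 and XAF1 by 0.76 ± 0.21. IRF7, a transcription factor of the interferon response, lost its call without HH (adjusted p = 0.0719) or H9 (0.124), HERC6 without PF382 (0.0658), TLOm1 (0.0936) or H9 (0.0502), and XAF1 without PF382 (0.0803), TLOm1 (0.084) or H9 (0.174). The nucleic acid sensors had 1 of 25 called (1 over the list alone, camera adjusted p = 0.563) and the genes of endogenous retroviral origin 0 of 10 (0 over the list alone, adjusted p = 0.614). MHC class I genes had 1 of 22 called (1 over the list alone, adjusted p = 0.164). Of 16 MHC class II genes 0 were called (0 over the list alone), while the list was higher by camera (adjusted p = 0.000928), and adjusted p = 0.508 with an estimated correlation. Among 31 checkpoint and costimulatory genes 2 rose and 2 fell (3 and 2 over the list alone, camera adjusted p = 0.926). Among 37 cytokines and chemokines 1 rose and 1 fell (2 and 1, adjusted p = 0.761). Among 34 T-cell receptor and identity genes 1 rose and 3 fell (2 and 3, adjusted p = 0.0857). In the last list THEMIS, a thymocyte signalling protein, fell by 1.59 ± 0.32 (adjusted p = 0.00433), and its call ended without PF382 (-1.55, adjusted p = 0.0579).

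Cell death and cell cycle lists had few members called at this azacitidine dose. They were 1 of 34 pro-apoptotic genes (lower), 0 of 11 anti-apoptotic genes, 1 of 26 p53 targets (higher), 1 of 52 cell cycle genes (higher) and 0 of 7 inhibitors of cyclin-dependent kinases, with 1, 0, 2, 0 and 0 over the list alone and camera adjusted p = 0.709, 0.971, 0.335, 0.209 and 0.924. Of 25 genes of the ATF4 and endoplasmic reticulum stress response 4 rose and 1 fell (6 and 1 over the list alone). The list was higher (camera adjusted p = 0.00539), with adjusted p = 0.366 with an estimated correlation and 0.103 without H9. Of 43 epigenetic enzymes 2 rose and 2 fell (2 and 3 over the list alone, camera adjusted p = 0.335), with the H3K27 demethylase KDM6B at -0.62 ± 0.10 (adjusted p = 0.000759). Of 28 genes of MYC and ribosome biogenesis 2 rose and 1 fell (2 and 1, adjusted p = 0.281). Of 24 NF-kB targets 0 rose and 1 fell (0 and 1, adjusted p = 0.209). Of 19 drug handling genes 0 rose and 2 fell (2 and 2, adjusted p = 0.728). Of 18 imprinted genes 1 rose and 1 fell (1 and 1, adjusted p = 0.971). None of 40 histone genes (0 over the list alone, adjusted p = 0.0878) or 6 metallothioneins (2 over the list alone, adjusted p = 0.0857) was called, and of 47 neuronal genes 2 were higher (1 over the list alone, adjusted p = 0.665).

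Markers of other cell types were measured beside these groups. At 250 nM azacitidine 2 of 10 epithelial markers rose (2 over the list alone, camera adjusted p = 0.0737), with the keratin KRT8 at 3.11 ± 0.46 (339 against 3230 counts, adjusted p = 0.000275). Of 11 myeloid markers 2 rose (3 over the list alone, adjusted p = 0.281), and of 15 markers of cytotoxic and natural killer cells 1 rose (1 over the list alone). The cytotoxic list was higher by camera (adjusted p = 0.00258), with adjusted p = 0.0806 with an estimated correlation and 0.156 without H9. Markers of B cells (0 of 12 called, 0 over the list alone), erythroid cells and megakaryocytes (0 of 6, 0 over the list alone) and fibroblasts (0 of 11, 3 higher over the list alone) had camera adjusted p = 0.728, 0.673 and 0.403.

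**Figure D1:**
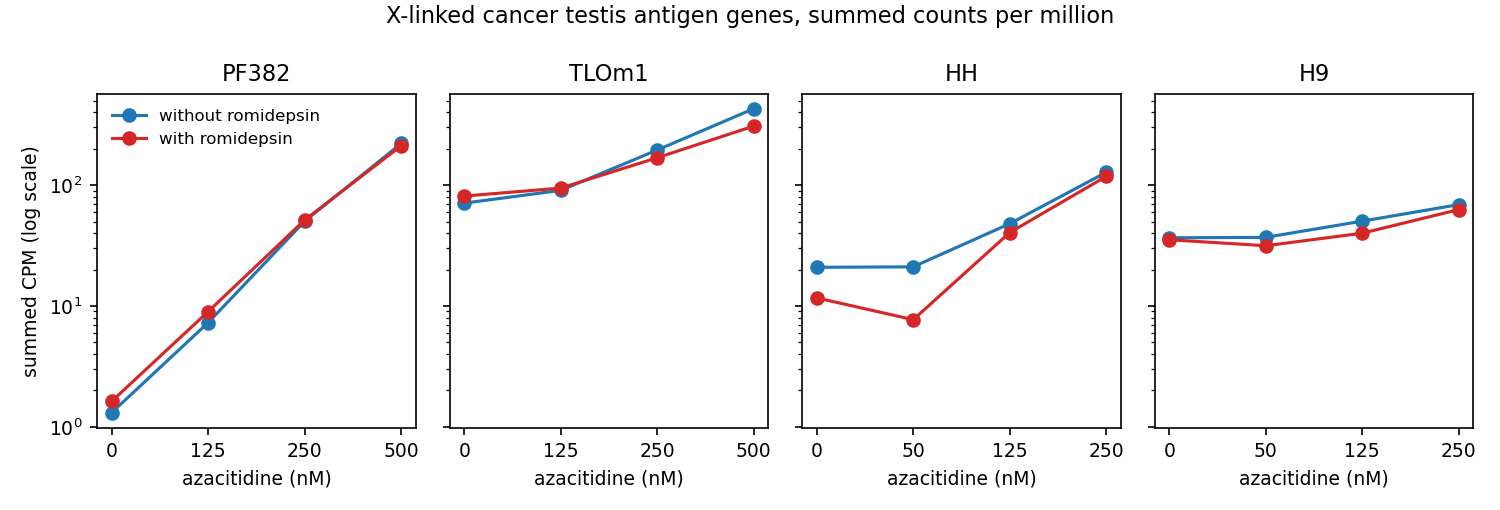
Summed CPM of the X-linked cancer testis antigen genes in each library (log axis) against the azacitidine dose in nM, by cell line, without and with romidepsin. The sum rose from 1.31 to 221 in PF382 and from 71 to 429 in TLOm1 between untreated cells and the highest azacitidine dose, and from 36.7 to 69 in H9.

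The response to azacitidine was graded with dose: per doubling of the dose within a line, 362 genes rose and 168 fell. The steepest increases were PNMA5 at 2.86 ± 0.23 per doubling (adjusted p = 3.33e-08), MAGEA4 at 2.68 ± 0.24 (adjusted p = 7.28e-08), MAGEC1 at 2.40 ± 0.33 and DAZL at 2.37 ± 0.33. PNMA5 was at 0.964, 10.8 and 60.7 CPM over the lowest, middle and highest doses of the 4 lines, and MAGEA4 at 0.157, 1.79 and 8.25. The PNMA5 values rest largely on PF382, which had 9293 counts of it in its 6 libraries with azacitidine. The steepest decreases were GRIP2 (42.2, 18.1 and 6.64 CPM, adjusted p = 0.0188), C6orf223 at -0.84 ± 0.13, ALDOC at -0.82 ± 0.20 (140, 115 and 39.8 CPM) and HMGCS1 at -0.77 ± 0.13 (270, 146 and 82.2 CPM). With dose, 40 of 49 X-linked cancer testis antigens rose (45 over the list alone), 18 of 47 germline genes rose (25 over the list alone), 19 of 23 cholesterol genes fell (21 over the list alone) and 8 of 25 ATF4 and stress response genes rose (14 over the list alone). With an estimated correlation the adjusted p was 0.0226, 0.0145, 0.0118 and 0.0226 for these lists. The stress response genes included DDIT3, which encodes the CHOP transcription factor (0.49 ± 0.09 per doubling), and the amino acid transporter SLC7A5 (0.34 ± 0.07). Leaving out 1 dose of 1 line left 204 genes (lowest dose of TLOm1), 273 (highest of HH), 314 (lowest of PF382), 316 (highest of TLOm1) or 330 (highest of PF382), and a stricter low-count filter left 349.

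The combination with azacitidine at 250 nM raised 2530 genes and lowered 1559 against untreated cells. MAGEA1 (383 counts) and CTAG2 (345 counts) had 0 counts in untreated cells and were at least 141-fold and 127-fold higher. COL14A1, a fibril-associated collagen, went from 1 to 725 counts (ratio 799, interval 143 to 31604) and NES, the intermediate filament nestin, from 3 to 506 (ratio 186, interval 63.2 to 904). SSX1 went from 3 to 523 counts (ratio 192, interval 65.4 to 935) and MAGEA4 from 1 to 173 (ratio 191, interval 33.8 to 7574), while BRDT rose by 7.38 ± 0.49 (adjusted p = 4.17e-09) and PNMA5 by 6.85 ± 0.67 (adjusted p = 1.02e-06). C6orf223 fell by 2.57 ± 0.34 (adjusted p = 2.95e-05), HMGCS1 by 2.41 ± 0.33 (adjusted p = 4.14e-05), ALDOC by 2.18 ± 0.42 (adjusted p = 0.000904), and SCD, the stearoyl-CoA desaturase of fatty acid synthesis, by 2.06 ± 0.21 (adjusted p = 1.21e-06).

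PFKFB4 fell by 2.53 ± 0.72 in the combination, and was not called without PF382 (-2.77, adjusted p = 0.0567), HH (-2.40, 0.0774) or H9 (-2.02, 0.0789). BNIP3, a mitophagy receptor, fell by 2.11 ± 0.57 and was not called without PF382 (-1.29, adjusted p = 0.097) or H9 (-2.11, 0.0551). The inhibitory receptor CD300A fell by 2.06 ± 0.53 and was not called without PF382 (-4.14, adjusted p = 0.0722), and PGLYRP4, a peptidoglycan recognition protein, fell by 1.89 ± 0.50 and was not called without HH (-1.56, 0.0731) or H9 (-1.90, 0.0561). Apart from BNIP3 without PF382, the estimates without a line stayed within 1.5 times the full one or, for CD300A, grew. Over all genes, 2598 were called without PF382, 2575 without HH and 63 in a fit of the 8 compared libraries alone. At 125 nM the combination changed 1246 genes and azacitidine alone 82.

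**Figure D2:**
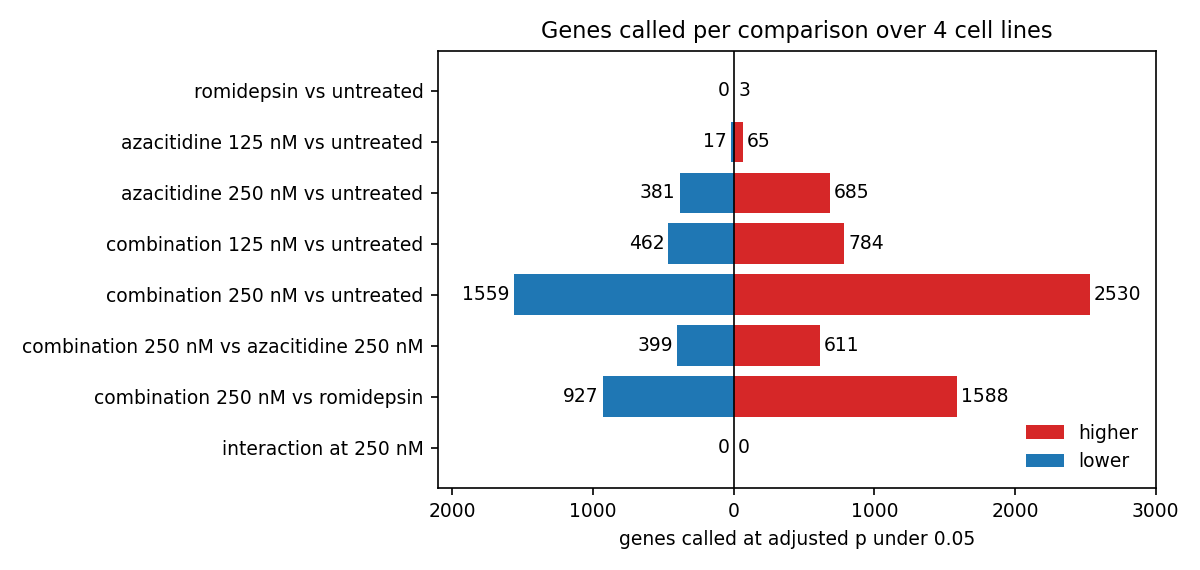
Number of genes called (adjusted p under 0.05) higher and lower in each comparison, drawn to the right and to the left of 0. The combination at 250 nM against untreated cells had 2530 higher and 1559 lower, azacitidine 685 and 381, and romidepsin alone 3 and 0.

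Cancer testis and germline genes rose in the combination: 33 of 49 X-linked antigens (36 over the list alone) and 20 of 47 germline genes (23 over the list alone), with 0 lower in either. In the combination at 250 nM the summed CPM of the X-linked antigens was 51.4, 169, 118 and 62.8 in PF382, TLOm1, HH and H9. With azacitidine alone at 250 nM it was 50.3, 195, 128 and 69. CTCFL went from 3 to 271 counts (ratio 99.6, interval 33.7 to 486) and TDRD1 from 1 to 135 (ratio 149, interval 26.3 to 5920). The camera adjusted p was 1.46e-12 and 1.19e-06, and adjusted p = 0.0549 and 0.0506 with an estimated correlation. Of 23 cholesterol genes 21 fell and 0 rose (21 over the list alone), among them LSS (-1.25 ± 0.12, adjusted p = 7.58e-07), FDFT1 (-1.43 ± 0.18, adjusted p = 1.49e-05) and the sterol sensor INSIG1 (-1.74 ± 0.22, adjusted p = 2.35e-05). Their camera adjusted p was 5.47e-20, and adjusted p = 0.0506 with an estimated correlation.

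Neuronal genes rose in 16 of 47 after the combination and fell in 0 (16 over the list alone, camera adjusted p = 0.000209, and adjusted p = 0.00809 with an estimated correlation, which was 0.073 without PF382). MAP2 rose by 4.64 ± 0.58 (adjusted p = 1.39e-05), UNC13A, a priming factor of synaptic vesicles, by 3.02 ± 0.46 (adjusted p = 0.000109), and CHGB by 2.06 ± 0.40 (adjusted p = 0.000896). Cytotoxic and natural killer markers rose in 11 of 15 (11 over the list alone, camera adjusted p = 8.26e-05, and adjusted p = 0.0152 with an estimated correlation, which was 0.0503 without TLOm1), among them the T-bet transcription factor gene TBX21 (4.39 ± 0.80, adjusted p = 0.000521). Markers of other lineages rose beside them. Of 11 myeloid markers 5 rose (6 over the list alone), with CD68 at 0.98 ± 0.19 (adjusted p = 0.000738). Of 11 fibroblast markers 4 rose (8 over the list alone), with fibronectin (FN1) at 2.28 ± 0.24 (adjusted p = 2.2e-06). Of 10 epithelial markers 3 rose and 1 fell (4 and 1 over the list alone), with KRT8 at 4.26 ± 0.47 (339 against 5153 counts). Their camera adjusted p was 0.0124, 0.0225 and 0.0228, and adjusted p = 0.0506, 0.182 and 0.154 with an estimated correlation. The myeloid call ended without PF382 (adjusted p = 0.116), the fibroblast call without HH (0.0755) and the epithelial call without TLOm1 (0.124) or H9 (0.07). Of 12 B-cell markers 3 rose and 1 fell (3 and 1 over the list alone, adjusted p = 0.204), and of 6 erythroid and megakaryocyte markers 2 rose (3 over the list alone, adjusted p = 0.391).

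Interferon-stimulated genes rose in 10 of 44 after the combination and fell in 0 (10 over the list alone). They included IFI6, an interferon-induced mitochondrial protein (1.56 ± 0.20, adjusted p = 2.14e-05), IRF7 (1.16 ± 0.24, adjusted p = 0.00164) and the oligoadenylate synthetase OAS3 (1.01 ± 0.21, adjusted p = 0.00198). The camera adjusted p was 0.00659, and adjusted p = 0.326 with an estimated correlation. Of 25 nucleic acid sensors 4 rose and 3 fell (5 and 3 over the list alone, adjusted p = 0.852). The 1 of 10 genes of endogenous retroviral origin that rose (1 over the list alone, adjusted p = 0.811) was the Gag-derived neuronal gene ARC (2.49 ± 0.58, adjusted p = 0.00405). MHC class I genes went both ways, with 7 of 22 higher and 4 lower (8 and 6, adjusted p = 0.804), and of 16 MHC class II genes 2 rose and 1 fell (2 and 1, adjusted p = 0.811). Among 31 checkpoint and costimulatory genes 5 rose and 1 fell (5 and 1, adjusted p = 0.142). CD274 rose by 2.86 ± 0.43 (adjusted p = 9.48e-05), TNFSF9, the ligand of 4-1BB, by 1.26 ± 0.29 (adjusted p = 0.00348), and TNFRSF14, the herpesvirus entry mediator, fell by 1.07 ± 0.16 (adjusted p = 6.92e-05). T-cell receptor and identity genes went both ways (5 higher and 5 lower of 34, 5 and 5 over the list alone, adjusted p = 0.142), with THEMIS at -1.71 ± 0.33 (adjusted p = 0.000833) and the adaptor LAT at 0.87 ± 0.19 (adjusted p = 0.00212). Of 37 cytokines and chemokines 11 rose and 3 fell (17 and 4, adjusted p = 0.142).

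Single genes of cell death, the cell cycle and stress responses changed in the combination, while the lists of pro-apoptotic genes, p53 targets and inhibitors of cyclin-dependent kinases were not called. The shares called among pro-apoptotic genes and p53 targets were near those over all genes, where 2530 of 17801 rose and 1559 fell. Of 34 pro-apoptotic genes 6 rose and 3 fell (8 and 3 over the list alone, camera adjusted p = 0.148). BAK1, an effector of the mitochondrial pathway, rose by 0.42 ± 0.07 (adjusted p = 0.000146), and the BH3-only genes BMF and PMAIP1 by 1.03 ± 0.19 (adjusted p = 0.000582) and 0.98 ± 0.20 (adjusted p = 0.00143). Of 11 anti-apoptotic genes 1 rose and 1 fell (1 and 1 over the list alone, adjusted p = 0.623), of 26 p53 targets 5 rose and 2 fell (5 and 2, adjusted p = 0.216). Inhibitors of cyclin-dependent kinases rose in 3 of 7 (3, adjusted p = 0.369), with CDKN1A, in both lists, at 1.39 ± 0.31 (adjusted p = 0.00315). Of 52 cell cycle genes 1 rose and 10 fell (1 and 10 over the list alone), such as the spindle checkpoint kinase BUB1B (-0.42 ± 0.07, adjusted p = 0.000296) and cyclin A2 (CCNA2, -0.49 ± 0.09, adjusted p = 0.000526). That list was lower (camera adjusted p = 0.0402), with adjusted p = 0.614 with an estimated correlation and 0.232 without PF382. Of 6 metallothioneins 5 rose (5 over the list alone, camera adjusted p = 0.00291, and adjusted p = 0.0506 with an estimated correlation), with MT2A at 1.62 ± 0.36 (adjusted p = 0.00279). The ATF4 and stress response list had 7 higher and 1 lower of 25 (7 and 1 over the list alone, camera adjusted p = 0.0225), with adjusted p = 0.291 with an estimated correlation and 0.255 without H9. Of 43 epigenetic enzymes 4 rose and 10 fell (6 and 10, adjusted p = 0.0558), and of 24 NF-kB targets 3 rose and 5 fell (4 and 8, adjusted p = 0.142). Of 28 genes of MYC and ribosome biogenesis 2 fell (0 over the list alone, adjusted p = 0.724), and of 19 drug handling genes 3 rose and 2 fell (4 and 3, adjusted p = 0.979). Of 40 histone genes 1 fell (0, adjusted p = 0.623), and of 18 imprinted genes 3 rose (3, adjusted p = 0.446).

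Adding romidepsin to azacitidine at 250 nM raised 611 genes and lowered 399 relative to azacitidine alone. The largest increases were FCER2, the low-affinity IgE receptor CD23 (3.8 ± 0.69, adjusted p = 0.0037), AKAP12, a scaffold of protein kinase A (3.71 ± 0.51, adjusted p = 0.000603), and HAP1, a huntingtin-associated protein (3.70 ± 0.63, adjusted p = 0.00261). They were followed by FAM131B (3.59 ± 0.58, adjusted p = 0.00171), the homeobox gene MEIS3 (3.57 ± 0.74, adjusted p = 0.00736), the Groucho corepressor TLE2 (3.53 ± 0.61, adjusted p = 0.0031), TJP3 of tight junctions (3.27 ± 0.76, adjusted p = 0.0154) and MAP2 (3.21 ± 0.49, adjusted p = 0.00114). MEIS3 was not called without H9 (adjusted p = 0.0516), and TJP3 not without PF382 (0.102) or HH (0.105). Decreases with 1 sign in 4 of 4 lines were smaller, and 7 of the largest were in CMAHP (-1.14 ± 0.25), the keratin KRT7 (-1.02 ± 0.24), the T-cell costimulation scaffold RLTPR (-0.90 ± 0.21), PHF15 (-0.85 ± 0.20), the nucleosome-binding HMGN5 (-0.80 ± 0.23), pericentrin (PCNT, -0.75 ± 0.21) and INSIG1 (-0.74 ± 0.22). Each of the 7 lost its call without HH (adjusted p from 0.0824 for CMAHP to 0.276 for HMGN5), 6 without PF382 (0.0518 for RLTPR to 0.106 for INSIG1) and 6 without TLOm1 (0.0682 for CMAHP to 0.262 for INSIG1). The estimate itself shrank by over 1.5 times for PHF15 (-0.48) and CMAHP (-0.73) without HH and for INSIG1 (-0.48) without TLOm1, and moved by less in the other losses of these 7. The count of genes called was 295 without PF382, 513 without TLOm1, 206 without HH and 639 without H9, and it was 58 at 125 nM. A fit of the 8 compared libraries alone called 0, and grouping doses by their order in each line called 2660 at the highest dose.

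When romidepsin was added to azacitidine, neuronal genes rose in 8 of 47 and fell in 0 (9 over the list alone, camera adjusted p = 1.55e-05, and adjusted p = 0.000983 with an estimated correlation). Of the checkpoint and costimulatory genes 4 of 31 rose (4 higher and 1 lower over the list alone), with CD28, the costimulatory receptor of T cells, at 1.60 ± 0.25 (adjusted p = 0.00137) and CD274 at 1.82 ± 0.39 (adjusted p = 0.00964), the latter not called without PF382 (0.0577) or TLOm1 (0.0919). That list was higher (camera adjusted p = 0.049), with adjusted p = 0.197 with an estimated correlation, and its call ended without PF382 (0.153), TLOm1 (0.263) or H9 (0.0842). IFI6 rose by 0.98 ± 0.20 (adjusted p = 0.00641) as the only interferon-stimulated gene called of 44, and BMF by 1.02 ± 0.19 (adjusted p = 0.00431) among 2 of 34 pro-apoptotic genes. Of 23 cholesterol genes 3 fell, of 52 cell cycle genes 2 fell and of 11 fibroblast markers 2 rose (3, 0 and 4 over the list alone), with FN1 at 1.61 ± 0.23 (adjusted p = 0.000944). The camera adjusted p of the last 3 lists was 0.00277, 1.13e-05 and 0.0399, and adjusted p = 0.465, 0.299 and 0.207 with an estimated correlation. The fibroblast call ended without PF382 (adjusted p = 0.153), TLOm1 (0.0748) or HH (0.133).

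Other lists moved in the same comparison. Cytotoxic markers had 2 of 15 higher, myeloid markers 1 of 11 and metallothioneins 0 of 6 (2, 3 and 5 over the list alone), with 0 lower in each. These lists were higher by camera (adjusted p = 0.0402, 0.0399 and 0.0399), and adjusted p = 0.207, 0.197 and 0.207 with an estimated correlation. The cytotoxic call ended without PF382 (0.168) or TLOm1 (0.197), the myeloid call without PF382 (0.16), TLOm1 (0.0861) or H9 (0.0842), and the metallothionein call without PF382 (0.18) or TLOm1 (0.0619). MHC class II genes had 0 higher and 1 lower of 16 (0 and 2 over the list alone), and the list was lower by camera (adjusted p = 0.00277, and adjusted p = 0.398 with an estimated correlation) although its median was 0.0042, and the call ended without HH (0.274). No more than 1 gene of the cancer testis list (PAGE2B, lower) and 1 of the germline list (BRDT, higher) was called. PAGE2B lost its call without PF382 (adjusted p = 0.0823), TLOm1 (0.198) or HH (0.119), and BRDT at 1.01 ± 0.29 lost its call without each line in turn (adjusted p = 0.136 without PF382, 0.0989 without TLOm1, 0.224 without HH and 0.0729 without H9).

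Adding azacitidine at 250 nM to romidepsin raised 1588 genes and lowered 927 relative to romidepsin alone. In HH this comparison also goes from 1 to 1.25 nM romidepsin, per the labels. MAGEA1 (0 against 383 counts) was at least 127-fold higher. SSX1 went from 1 to 523 counts (ratio 519, interval 92.8 to 20551), CTAG2 from 1 to 345 (ratio 343, interval 61.1 to 13570), NES from 2 to 506 (ratio 251, interval 69.2 to 2080) and BRDT from 3 to 701 (ratio 232, interval 79.1 to 1130). PNMA5 rose by 7.50 ± 0.72 (adjusted p = 1.26e-06). C6orf223 (-2.21 ± 0.34), HMGCS1 (-2.02 ± 0.33), SCD (-1.80 ± 0.21), INSIG1 (-1.37 ± 0.22) and MMAB, a cobalamin adenosyltransferase (-1.37 ± 0.20), fell with adjusted p from 1.08e-05 (SCD) to 0.000419 (INSIG1). PDK1, an inhibitor of pyruvate dehydrogenase, fell by 1.55 ± 0.33 and was not called without H9 (adjusted p = 0.0519). Leaving out 1 line left 1628 (PF382), 1444 (TLOm1), 1327 (HH) or 1431 (H9) genes, and at 125 nM 255 were called. A fit of the 8 compared libraries alone called 92, and grouping doses by their order in each line called 4879 at the highest dose.

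In the same comparison, 30 of 49 X-linked cancer testis antigens rose (35 over the list alone), 18 of 47 germline genes rose (19), 20 of 23 cholesterol genes fell (21 lower and 1 higher), 6 of 15 cytotoxic markers rose (10) and 3 of 10 epithelial markers rose with 1 lower (6 and 1). These 5 lists were called with an estimated correlation too (adjusted p = 0.0438, 0.0438, 0.0462, 0.0203 and 0.0438). Those calls ended without TLOm1 in each list (0.13, 0.13, 0.138, 0.0546 and 0.138). For cancer testis, germline and cholesterol genes they also ended without PF382 (0.186, 0.151 and 0.141) or HH (0.168, 0.125 and 0.078), for epithelial markers without HH (0.078) or H9 (0.193), and for cholesterol genes without H9 (0.107). Neuronal genes (6 of 47 higher, 5 over the list alone) and myeloid markers (5 of 11 higher, 6 over the list alone) were called too, by camera (adjusted p = 0.0084 and 0.0127) and with an estimated correlation (0.0421 and 0.0438). With that correlation both calls ended without PF382 (0.151 and 0.231), TLOm1 (0.13 and 0.155) or HH (0.051 for each), and the myeloid one without H9 (0.109), while by camera the myeloid call ended without PF382 (0.121) or TLOm1 (0.0732).

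The other lists called by camera over romidepsin lost the call with an estimated correlation. Interferon-stimulated genes rose in 5 of 44 (4 over the list alone), metallothioneins in 2 of 6 (3), ATF4 and stress response genes in 7 of 25 (8) and fibroblast markers in 3 of 11 (5), with 0 lower in each, and cell cycle genes fell in 6 of 52 and rose in 1 (9 and 3). Their camera adjusted p was 0.00949, 0.0084, 0.00348, 0.00949 and 0.0448, and adjusted p = 0.283, 0.0554, 0.162, 0.162 and 0.755 with an estimated correlation. By camera the fibroblast call ended without HH (0.0569), the stress response call without H9 (0.102) and the cell cycle call without PF382 (0.081) or TLOm1 (0.193).

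No gene departed from the sum of the single-drug log2 changes at 250 nM by edgeR, with 0 of 17801 called, 0 by DESeq2 and 0 by limma-voom, and 596 genes (3.35%) at an unadjusted p under 0.05. HH was labelled with 1 nM romidepsin alone and 1.25 nM in its combinations, so its departures include that step in dose. Simulated departures were recovered for 67 of 100 genes at 2-fold, with 22 false calls in that simulation. They were set to be the same in every line, so recovery of departures that differ between lines is not known. BMF, at 1.18 ± 0.27 in 4 of 4 lines, was the 1 pro-apoptotic gene higher when adjusted over its list of 34 alone. Neuronal genes lay above additivity as a list (28 of 47 with a positive estimate, camera adjusted p = 0.00967, and adjusted p = 0.0239 with an estimated correlation), a call that ended without H9 (adjusted p = 0.113). With an estimated correlation it ended without PF382 (0.3), HH (0.25) or H9 (0.324). Cell cycle genes (47 of 52 with a negative estimate) and genes of MYC and ribosome biogenesis (26 of 28) lay below it (camera adjusted p = 4.04e-07 and 4.95e-05), with adjusted p = 0.342 and 0.542 with an estimated correlation, and the latter call ended without PF382 (0.109).

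Within the combination, 1158 genes rose and 625 fell per doubling of the azacitidine dose. With library totals as the only scaling the split was 1367 higher and 411 lower. MAGEA4 rose by 2.99 ± 0.25 per doubling (adjusted p = 5.45e-08; 0.0919, 0.82 and 6.21 CPM over the lowest, middle and highest doses), PNMA5 by 2.57 ± 0.24, DAZL by 2.36 ± 0.35 and SSX1 by 2.36 ± 0.28. CACNA2D3, a calcium channel subunit, fell by 1.24 ± 0.38 per doubling (2.43, 1.29 and 0.273 CPM), the leukotriene receptor CYSLTR2 by 0.85 ± 0.26 and PRKCDBP by 0.71 ± 0.18. Of the lists, 41 of 49 X-linked cancer testis antigens and 23 of 47 germline genes rose (48 and 28 over the list alone), 11 of 23 cholesterol genes fell (18 lower and 1 higher) and 10 of 52 cell cycle genes fell (24). ATF4 and stress response genes rose in 10 of 25 (16), 7 of 47 neuronal genes rose (12), 6 of 11 fibroblast markers rose (7) and 4 of 28 genes of MYC and ribosome biogenesis fell (10). With an estimated correlation none of these 8 lists was called (adjusted p = 0.0948, 0.0841, 0.152, 0.319, 0.152, 0.0841, 0.188 and 0.407). Leaving out 1 dose of 1 line left 444 genes (lowest of TLOm1), 691 (highest of HH), 698 (highest of TLOm1), 923 (lowest of PF382), 977 (highest of PF382) or 988 (lowest of HH), and without the lowest dose of H9 2499 were called. A stricter low-count filter left 1111, and dose on a linear scale gave 2913.

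Within each line, 4 libraries with romidepsin were compared with 4 without, matched on azacitidine dose, with dose levels as replicates in place of lines. In PF382 3406 genes rose and 2067 fell, in TLOm1 3047 and 2761, in HH 2498 and 2430, and in H9 648 and 148. In fits of the 8 libraries of a line alone, H9 had 1514 higher and 1390 lower, 2904 in all against 5185 in PF382, 3933 in TLOm1 and 4042 in HH, so the larger share of increases in H9 did not hold there. In PF382 the neural adhesion molecule L1CAM rose by 5.48 ± 0.29 (0.34 against 16.5 CPM) and the p53 relative TP73 fell by 2.73 ± 0.17. MEIS3 and the complement gene C3 had 0 counts without the drug in PF382 and were at least 38.4-fold and 23-fold higher. In TLOm1 the teneurin ODZ3 rose by 4.70 ± 0.22 (0.506 against 13.7 CPM), and NPAS2, a circadian transcription factor, was at least 4.41-fold higher. In HH interferon gamma (IFNG, 0 against 25 counts) and the kinase LCK (0 against 24 counts) were at least 9.07-fold and 8.71-fold higher, while RSAD2, the antiviral protein viperin, went from 19 counts to 0, at least 5.82-fold lower. In H9 MEIS3 rose by 2.94 ± 0.27, the costimulatory ligand CD86 was at least 3.72-fold higher (0 against 10 counts), and the collagen COL6A1 fell by 1.90 ± 0.25 (29.7 against 8.87 CPM).

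The romidepsin effect differed between lines for 5878 genes, a test that cannot part the line from its romidepsin dose, and the effect in HH mixes 2 doses. In all, 99 genes rose and 19 fell in 4 of 4 lines, against 2.98 and 0.364 if the calls were independent. The lines share 1 estimate of the spread per gene, so calls can overlap without a shared response and these expected counts can be too low. Genes that rose in each line included AKAP12, SEMA6B, SRRM3, EPHB2 and CD28, and among those that fell were LSS, by 0.41, 0.58, 0.57 and 0.39 in PF382, TLOm1, HH and H9, and MALT1, a scaffold and protease of antigen receptor signalling. Genes called higher in 1 line and lower in another numbered 939. MHC class II genes went in opposite directions: 9 of 16 rose and 1 fell in PF382 and 10 rose and 0 fell in H9, while 0 rose and 9 fell in TLOm1 and in HH. HLA-DPA1 rose by 1.01 ± 0.09 in H9 and by 1.39 ± 0.23 in PF382, and the class II transactivator CIITA fell by 0.82 ± 0.15 in TLOm1 and by 0.67 ± 0.15 in HH. With an estimated correlation the list was not called in any line (adjusted p = 0.585, 0.498, 0.279 and 0.544 in PF382, H9, TLOm1 and HH). Neuronal genes rose in 21, 16, 13 and 10 of 47 and fell in 2, 5, 2 and 0 in PF382, TLOm1, HH and H9. In TLOm1 20 of 40 histone genes rose and 0 fell. Cholesterol genes fell in 18, 9, 20 and 1 of 23 in the same order of lines and rose in 0, 0, 0 and 1. Of 24 NF-kB targets 11 fell and 1 rose in HH, with the chemokine CCL22 at -3.24 ± 0.20. With an estimated correlation none of these lists was called in the 4 lines, with the lowest adjusted p = 0.0771 for cholesterol genes and for NF-kB targets in HH. In H9, 456, 364 or 287 genes were called without the lowest, middle or highest azacitidine dose, and 3078 in PF382 and 3631 in TLOm1 without the highest.

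**Figure D3:**
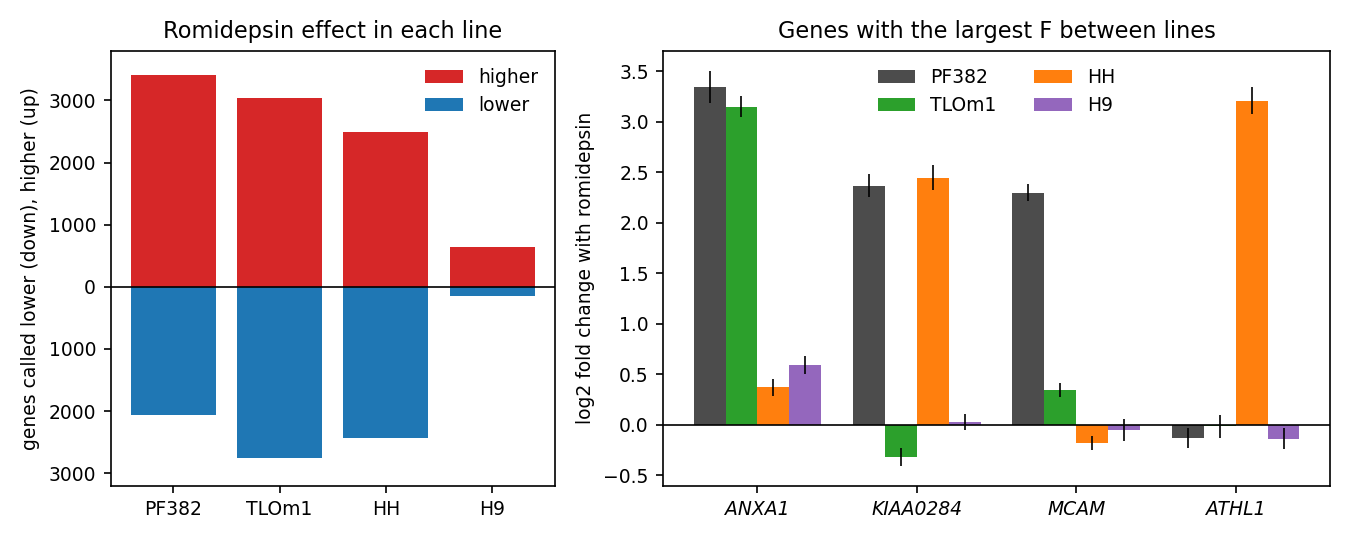
Left, number of genes called higher and lower after romidepsin in each cell line, from 3406 and 2067 in PF382 to 648 and 148 in H9 (1514 and 1390 when H9 was fitted alone). Right, log2 fold change with its standard error of ANXA1, KIAA0284, MCAM and ATHL1 per line, the 4 genes whose romidepsin effect differed most between lines.

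Azacitidine at any dose, 6 libraries against 2 in each line, raised 1058 genes and lowered 425 in PF382, 1961 and 1368 in TLOm1, 724 and 321 in HH, and 500 and 544 in H9, with dose differences counted as spread and, in HH, the higher romidepsin dose of the combinations included. The order of the lines depended on the fit: with the 8 libraries of a line alone 1297 genes were called in PF382, 510 in TLOm1 (442 higher, 68 lower), 362 in HH and 1177 in H9. In H9 more genes rose than fell with library totals as the only scaling (598 and 509) and with DESeq2 (959 and 811), which called 1684 in HH. In PF382 CTAG2 was at least 79.9-fold higher (0 against 784 counts), GTSF1, a germline factor of the piRNA pathway, rose from 4 to 3058 counts, BNIP3 fell by 2.84 ± 0.47 and the interleukin receptor IL7R fell by 2.36 ± 0.43 (13.2 against 2.61 CPM). TLOm1 had SSX1 at least 255-fold, SSX3 at least 135-fold, MAGEC1 at least 128-fold and MAGEA1 at least 107-fold higher, and TCF7, a transcription factor of T-cell identity, fell by 3.86 ± 0.28 (adjusted p = 3.64e-09). In HH H19 was at least 186-fold higher (0 against 1696 counts). In H9 C1orf106 rose by 4.50 ± 0.86 and KRT8 by 3.75 ± 0.82, and KATNAL2, a katanin subunit, fell by 1.83 ± 0.20. Interferon-stimulated genes rose in 18 of 44 in TLOm1, with 1 lower, in 7 of 44 in PF382, in 5 with 1 lower in HH and in 0 in H9, and MHC class I genes in 7 of 22 in PF382, among them HLA-B (1.22 ± 0.17). In H9 8 of 16 MHC class II genes rose, among them HLA-DRA (1.81 ± 0.22), and 5 of 15 cytotoxic markers rose, such as the transcription factor EOMES (1.11 ± 0.18). With an estimated correlation the adjusted p was 0.617 for interferon genes in TLOm1, 0.576 for MHC class I in PF382, 0.292 for MHC class II in H9 and 0.0262 for cytotoxic markers in H9.

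The azacitidine effect differed between lines for 1904 genes, with line and dose range not separable, and this number and the number called in a line moved with the dose left out. It was 3177 without the lowest dose of TLOm1, 1217, 1202 and 1164 without the middle dose of TLOm1, HH and H9, and 3523 with DESeq2. Without a line's own lowest and highest dose the calls were 2244 and 771 in PF382, 5206 and 2010 in TLOm1, 2042 and 504 in HH and 2023 and 362 in H9, and without the middle dose 955 in PF382, 569 in HH and 508 in H9. Without the highest dose of TLOm1 1653 genes were called in H9. The number of X-linked antigen genes with at least 10 counts rose from 0 to 39 in PF382, from 1 to 48 in TLOm1, from 3 to 25 in HH and from 3 to 9 in H9 between untreated cells and the highest azacitidine dose, and was 1, 2, 2 and 2 after romidepsin alone. In the highest-dose combination it was 36, 39, 27 and 5 in the same order of lines. The summed CPM of these antigens was 212, 308, 118 and 62.8 there, against 221, 429, 128 and 69 at the highest dose of azacitidine alone.

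Transcripts of the drugs' own targets were measured too. DNMT1, the maintenance DNA methyltransferase, was at 0.17 ± 0.07 after azacitidine at 250 nM (adjusted p = 0.138) and at 0.09 in the combination. The de novo methyltransferase DNMT3B rose by 2.05 ± 0.37 in the combination (2937 against 10046 counts, adjusted p = 0.000571), and was at 0.84 ± 0.37 after azacitidine alone (adjusted p = 0.181). In HH romidepsin raised DNMT3B by 3.01 ± 0.48 and DNMT3A by 2.13 ± 0.19. HDAC1 rose by 0.22 ± 0.06 in the combination (adjusted p = 0.00997), and was not called without PF382 (0.0857), TLOm1 (0.0684) or HH (0.142).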

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

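The test of depth below was chosen only after the result was seen. The romidepsin effect differed between the 4 lines for 5878 genes by a test of the difference itself, with libraries matched on azacitidine dose as replicates. The lines were not given 1 romidepsin dose: PF382 had 1.25 nM, TLOm1 and H9 1 nM, and HH 1 nM alone and 1.25 nM in its combinations, so line and dose cannot be parted. The largest F values were those of ANXA1, an annexin that limits inflammation (F = 218), KIAA0284 (F = 199), MCAM, an adhesion molecule (F = 183), and ATHL1 (F = 177). ANXA1 rose by 3.35 ± 0.16 in PF382, 3.15 ± 0.10 in TLOm1, 0.37 ± 0.09 in HH and 0.59 ± 0.09 in H9. KIAA0284 rose by 2.37 ± 0.12 in PF382 and 2.45 ± 0.12 in HH, fell by 0.32 ± 0.09 in TLOm1 and was at 0.03 in H9. MCAM rose by 2.30 ± 0.09 in PF382 and ATHL1 by 3.21 ± 0.13 in HH, with at most 0.34 and -0.01 in the other lines.

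The azacitidine effect differed between lines for 1904 genes by the same kind of test, which takes the 3 doses of a line as replicates although the doses of PF382 and TLOm1 were higher than those of HH and H9, and the HH combinations had more romidepsin than its single drug. The largest F values were those of SULT1A1, a sulfotransferase (F = 68.9), TCF7 (F = 58.8), GALNT5, a glycosyltransferase (F = 51.9), and LRRN3, a leucine-rich repeat protein (F = 46). SULT1A1 rose by 5.64 ± 0.37 and TCF7 fell by 3.86 ± 0.28 in TLOm1, and GALNT5 rose by 4.27 ± 0.28 in HH. LRRN3 rose by 4.64 ± 0.46 in TLOm1 and by 2.67 ± 0.33 in HH and was at -0.65 in H9.

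In groups of 4 samples, 127 were tested for 1 value far from the other 3, and 7 had one; chance alone gives about 1 in 20. DNMT3A changed by 1.63 in HH after romidepsin alone, against -0.20 to 0.00 in the other lines, and DNMT3B by 0.96, against 0.33 to 0.37. For DNMT3B in HH the change was 3.89 in the combination over azacitidine at 250 nM (0.62 to 0.91 in the others), and the departure from additivity was 2.92 (0.29 to 0.54 in the others), with the HH combinations labelled at 1.25 nM romidepsin and the single drug at 1 nM. For DNMT1 the combination over azacitidine was at -0.024 in H9 (-0.10 to -0.09 in the others), and the departure from additivity was at -0.18 in HH (-0.04 to -0.02 in the others). The HH library at azacitidine 125 nM had a total of 32.5 M counts, against 24.3 to 25.5 M in the other lines. No explanation of these 7 values was tested.

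Few genes (3) were called for romidepsin alone across the lines, from 1 treated and 1 untreated library per line. The 796 to 5808 genes called within lines come from 4 against 4 libraries, 3 of each with azacitidine, so the counts are not of 1 kind. Romidepsin libraries of cells without a drug response do not account for this. Across 13092 genes, the change after romidepsin alone correlated with the mean change of the combinations over azacitidine, which share no library with it, at 0.625 in PF382, 0.489 in TLOm1, 0.608 in HH and 0.570 in H9. A correlation does not show whether the response alone was as large. In the same order of lines, 451, 485, 538 and 231 of these genes changed at least 2-fold alone. In the combinations over azacitidine 1049, 709, 733 and 225 did, so a smaller response alone is not excluded in PF382, TLOm1 and HH. Lower depth does not account for the few calls either, since the romidepsin libraries held 90.1% of the counts of the untreated ones. Lines that respond with different genes could be the cause. The median correlation of the romidepsin effects over 6 pairs of lines was 0.269. It lay between the bounds of 0.2 and 0.5 set for different and for shared responses, so it does not decide. The effects did differ between lines for 5878 genes, and 939 were called in opposite directions, beside 99 higher and 19 lower in 4 of 4 lines. Whether these differences account for the few calls was not tested.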

How the results depend on the processing

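Among 302 named gene results of the first model, 0 changed direction with DESeq2, limma-voom, library totals, no cell line term or a line left out. A change of sign counted only where the gene was called in the main or the other fit. Genes named for slopes and single lines were not part of these results. Those named for the largest changes had been chosen among called genes with the same sign in every line. Leaving out a line could thus hardly reverse them, and the absence of reversals says little on that point. Over 3 scalings 25 of 496 list medians changed sign, none of them over 0.0349 from 0. For azacitidine in H9 (500 higher, 544 lower) more genes rose than fell with library totals (598 and 509), DESeq2 (959 and 811), without its lowest dose (1012 and 1011) and without the highest dose of TLOm1 (834 and 819). For romidepsin in HH (2498 and 2430) the balance turned without a low-count filter (2281 and 2283). DESeq2 and limma-voom kept the side of the threshold for 285 and 279 of 302 named gene results, library totals as the only scaling for 292, and the fit without PF382, TLOm1, HH and H9 for 220, 237, 204 and 235. Of 46 list calls by camera 14 stayed with an estimated correlation between members. The test for departure from additivity called 0 genes under every setting, with a range of 0 to 0 over left-out lines. Other counts of genes that stayed within 1.5 times the main count are not listed.

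For romidepsin against untreated cells (3 genes) DESeq2 and limma-voom called 9 each, grouping the azacitidine libraries by dose order in place of nM 6, and a fit of these groups alone 16. For azacitidine (1066), the combination (4089), the combination over azacitidine (1010) and over romidepsin (2515), 125 nM in place of 250 nM gave 82, 1246, 58 and 255. Each line's highest dose in their place gave 1940 for azacitidine, 2660 for the combination over azacitidine and 4879 for the combination over romidepsin. Fits of the compared groups alone gave 30, 63, 0 and 92. Without the cell line as a block the 5 counts were 0 for romidepsin, 1 for azacitidine, 5 for the combination, 0 over azacitidine and 1 over romidepsin, since differences between lines then count as spread. A stricter filter gave 349 genes for the azacitidine slope (530) and 1111 for the combination slope (1783), and dose on a linear scale 2913 for the latter. The line's 8 libraries alone gave 2904 genes for romidepsin in H9 (796), 510 for azacitidine in TLOm1 (3329) and 362 in HH (1045). DESeq2 called 1684 genes for azacitidine in HH, 1770 in H9 (1044) and 3523 for the difference between lines (1904). Smaller fits moved the counts both ways. Apart from the block, the cause of these shifts was not tested.

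Leaving out 1 line gave 0 to 3 genes for romidepsin, 454 to 679 for azacitidine, 2575 to 3084 for the combination, 206 to 639 for the combination over azacitidine and 1327 to 1628 over romidepsin. Leaving out 1 dose of 1 line gave 204 to 486 for the azacitidine slope and 444 to 2499 for the combination slope. For the romidepsin effect it gave 3078 to 6075 in PF382, 3631 to 6043 in TLOm1, 3360 to 5460 in HH, 287 to 1101 in H9 and 4907 to 5988 for the difference between lines. For the azacitidine effect it gave 771 to 2244, 2010 to 5206, 504 to 2042 and 362 to 2023 in the same order, and 1164 to 3177 for the difference. With 1 library per condition and line, changes of 2-fold in romidepsin alone were recovered for 77 of 100 simulated genes, which changed alike in every line.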

Other observations

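The test of library depth and both tests of the hypoxia-type genes below were chosen only after the results were seen. Romidepsin effects were compared between pairs of lines, which share no libraries. PF382 and TLOm1 shared 1067 genes called higher and 769 called lower, against 583 and 321 if independent, and TLOm1 and HH 1068 and 1079, against 428 and 377. Genes called in both but in opposite directions numbered 396 and 256 in these pairs, against 882 and 803 if independent. Opposite calls numbered 475 in PF382 and HH, 20 in PF382 and H9, 75 in TLOm1 and H9, and 81 in HH and H9. If independent they would number 755, 104, 126 and 109. Since the lines share 1 estimate of the spread per gene, counts expected with independence can be too low for calls in both lines. Genes higher in 4 of 4 lines included SYT7 and SNAP25 of synaptic vesicle release, the scaffold HOMER3 of synapses and TEX19, a germline gene.

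More genes had a count at higher azacitidine doses. With every library thinned to the smallest total, untreated cells, the highest azacitidine dose and the highest-dose combination had 17052, 18172 and 19314 genes in PF382, 17046, 18447 and 19521 in TLOm1, 16376, 17046 and 17760 in HH, and 16603, 16800 and 17170 in H9. Library depth does not account for this, since the combination exceeded untreated cells in 4 of 4 lines at equal depth. Genomic DNA in the libraries was judged by the summed CPM of 372 olfactory receptor genes in the highest-dose combination over untreated cells. The ratio was 0.799 in PF382 and 0.708 in H9, so genomic DNA does not account for the rise in these lines. In TLOm1 and HH the ratio was 1.88 and 1.39, so a contribution of genomic DNA cannot be excluded there. Mixing with the other 3 lines was tested on part of the rise, the genes at 0 counts in untreated cells and at 10 or more in the highest-dose combination (596 in PF382, 513 in TLOm1, 273 in HH and 58 in H9). It does not account for most of these, since at most 42.9% (in HH) were at 1 CPM or more in untreated cells of at least 1 of the other lines. The remaining genes, and lines from outside the series, were not tested. Loss of silencing by the 2 drugs was not tested.

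Glycolysis and hypoxia-type genes were lower with azacitidine and the combination at 250 nM: PFKFB4, ALDOC, AK4, DDIT4 and PDK1 in both and BNIP3 in the combination. In the combination AK4 was lower in 2 of 4 lines only. Calls of PFKFB4, AK4 and DDIT4 after azacitidine, and of PFKFB4 and BNIP3 in the combination, ended without single lines, as given above. A list of 34 other hypoxia-induced genes, chosen after those 6 were seen, had 0 higher and 18 lower after azacitidine at 250 nM and 2 higher and 21 lower after the combination. Scaling of the libraries does not account for the pattern, since with library totals as the only scaling 18 of the 34 were lower after azacitidine and 21 after the combination, as were 5 and 6 of the 6 seen first. Lower hypoxia-inducible factor activity may be the cause, and it cannot be told apart from other causes here: the list had adjusted p = 0.166 with an estimated correlation in the combination (4.09e-11 with the preset one). Oxygen, cell density and cell counts are not given in the sources used here.

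Each comparison was repeated with the libraries split in other ways. In the comparisons of 4 against 4 libraries the lines pair the libraries, and 8 of 35 splits part each line as the real one does, too few for a share under 0.05. Among these 8 the highest other count was 41 for azacitidine (1066 real), 393 for the combination (4089), 2 for the combination over azacitidine (1010), 113 over romidepsin (2515) and 1 for romidepsin against untreated cells (3). The other splits keep both libraries of at least 1 line together, and with them the real count was reached by 1 of 35 splits in the first 4 comparisons, the real one, and by 6 of 35 for romidepsin. The highest there, 728 for romidepsin, kept the 2 libraries of every line together. The same grouping of the lines called 0 for azacitidine and 0 for the combination against untreated cells, and the cause was not tested. For the romidepsin effect within a line 8 of 32 splits part the 4 dose pairs, also too few, with at most 1414 (PF382, 5473 real), 1125 (TLOm1, 5808), 210 (HH, 4928) and 2 (H9, 796) in the others. Splits that part 2 pairs compare those pairs alone and gave up to 3884, 5067, 3313 and 32. For the slopes of azacitidine (530) and of the combination (1783) the other draws of 40 called at most 4 and 6. For the differences between lines in romidepsin (5878) and azacitidine effect (1904) they called at most 185 and 501. No other draw reached the real count in these tests, but 40 draws are few. A batch or culture difference of a whole line was not tested by them. For departure from additivity (0) 20 of 20 draws called as many, so nothing follows on chance. The highest was 2670, and its cause was not tested.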
